A study of Mus musculus with 4 samples.

How the data were processed

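Single-cell RNA libraries of mouse liver were compared: 4 libraries, 1 for each combination of 2 genotype labels (Mef2d KO and WT) and 2 stages (premalignant liver and eHCC). Per the labels, tissue was dissociated and polyadenylated RNA was read with 10x Genomics 5' gene expression chemistry. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.1 per the file headers; no normalisation had been applied to them. The submitters' processing notes name bcl2fastq 2.20.0, Cell Ranger and the builds GRCh38 and mm10, without giving the role of each build; the gene identifiers in the files are mouse Ensembl identifiers. The files list 31053 genes; 71 of the symbols are not unique and were kept apart by identifier. The lowest total per barcode was 500, 501, 500 and 500 UMIs in the KO premalignant, WT premalignant, KO eHCC and WT eHCC libraries, the order used throughout this section. The number of animals behind each library is not given in the sources used here.

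Grouping, comparisons, cell filters, marker lists, 49 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Cells had at least 500 UMIs, at least 300 genes and at most 25% of UMIs from mitochondrial genes. In all, 52, 239, 1591 and 434 barcodes were under the gene minimum, 123, 216, 132 and 306 were over the mitochondrial limit, and 9497, 13712, 8963 and 10282 passed. Doublets were called per library with scrublet in scanpy. Its own threshold marked 7.09% and 6.12% in the premalignant libraries. In the eHCC libraries it marked 0.011% and 0.0094%, under the 0.5% set as a minimum, so a top share set at 0.8% per 1000 cells was taken (7.28% and 8.47%). Cells with a score tied at the cut were not marked, which left 6.80% and 8.23%. This removed 678, 844, 595 and 821 of the passing cells. The kept cells had medians of 1823, 1948, 2082 and 2329 genes and of 4.27%, 4.66%, 3.87% and 5.35% mitochondrial UMIs.

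The 4 libraries were clustered together without batch integration: counts scaled to a sum of 10000 per cell and log-transformed, 2000 variable genes without receptor segment, mitochondrial and sex-linked genes, values scaled to at most 10, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0. This gave 36 clusters. Clusters were named from 25 marker lists, with a pseudocount of 5 CPM, at least 3 detected markers and a marker counted as detected in at least 10% of cells. Phagocytes were clustered again into 18 clusters and epithelium, at resolution 0.5, into 6. The Kupffer name required both Clec4f and Timd4. The naming rule was written and revised in 4 versions after cell numbers per class and library had been seen; the second clustering, the required markers and the limit of 0.25 on a competing class were part of these revisions. Earlier versions were run as alternatives. A cluster that carried Kupffer and LSEC markers (17, 267, 0 and 0 cells) and one with Kupffer and B cell markers (12, 13, 3 and 0 cells) were left out of the Kupffer-like class. Values were also rounded before clustering so that repeated runs give the same output; this changed the clusters after first results had been seen. Some named genes of premalignant phagocytes changed, dendritic cells and the main proliferating cluster lost their names, and the oncofetal value became smaller in size. An unnamed low-UMI cluster with hepatocyte RNA (930, 887, 3 and 5 barcodes) was chosen for the hepatocyte lists after the data were seen, since no hepatocyte-like class reached 100 cells.

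Shares of cells have exact Clopper-Pearson intervals, CPM exact Poisson intervals, and log2 ratios of CPM between UMI sums of a class exact conditional binomial intervals, all at 95%. A gene with 0 UMIs in 1 library was set against a floor of 3 UMIs and its ratio given as a bound. Intervals and floors cover counting error only. With 1 library per group no test between groups was run and no count of changed genes is given. An additive model of genotype and stage would leave 1 residual degree of freedom and use the stages as replicates; it was not run. A list was summarised by the median log2 ratio of its members with at least 20 counts in both libraries together, if at least 5 had them. The median was placed among 10000 random lists of the same size matched on expression in 25 bins, and called when it lay in the lowest or highest 2.5% of them. This describes the libraries and does not test genotype. Of 49 lists, 45 had a value in at least 1 class, and 202 medians were computed outside the free RNA lists and the low-UMI cluster. Classes needed 100 cells in both libraries. Proliferation was counted as cells with at least 3 UMIs of S and G2/M phase genes after thinning to 1000 UMIs, in 8184, 12287, 8218 and 9330 cells.

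Genes were named by size. A gene needed 50 counts in both libraries together, and a CPM of at least 0.1 of its highest value in any class in at least 1 library. Receptor segment, haemoglobin, mitochondrial, ribosomal protein, sex-linked and unnamed-model genes were excluded. Genes were ranked by the interval bound nearest 0. The 3 highest and 3 lowest were taken for each genotype comparison in phagocyte-like cells and in the other 2 named classes with the most cells in their smaller library, and for each stage comparison in phagocyte-like cells, as were the 2 highest and 2 lowest with the same direction at both stages. Of each described list up to 4 members could be given as examples, and 20 genes, among them Mef2d, Cd274, Trem2, Pdcd1, Gzmb and Foxp3, could be named wherever measured. Proliferating and unnamed clusters were not counted among the largest classes, a choice made after they were seen. An error that let a gene with 0 counts meet the second condition was corrected after named genes had been seen; 1 gene, Mcpt4, left the named set. For 2 of the tests in the closing section, those on subsets of cells and on the 10 highest cells, the interval used to judge the value was added after the value was seen. Marco, Cd5l and their library-wide values were chosen after Kupffer-like cells had been counted.

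Alternatives were median-of-ratios and TMM scaling, other cell filters, doublets kept, thinning to 1000 UMIs, clustering per library, other resolutions and another seed, equal weight per cell, other count minima, removal of the cell with the most UMIs of a gene in each library and the MEF2 list without its immediate-early genes (both added after the data were seen), means in place of medians, and immune cells as the denominator of shares. The interval method was tested on simulated data with 200 changed genes: 95.5% to 95.8% of unchanged genes had intervals that held the true ratio, 77.6% to 88.1% of genes changed 1.5-fold were recovered, and 1% to 7% of unchanged lists lay outside the central range. The simulated counts were Poisson draws with independent genes and no spread between cells. They check the computation, and cannot show that the intervals or random ranges hold for these data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.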

Results

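RNA of single cells was measured in 4 mouse liver libraries made with 10x Genomics 5' gene expression chemistry, as the labels give it. Each library is the only one of its group: the groups cross 2 genotype labels (Mef2d KO and WT) with 2 stages, premalignant liver and early hepatocellular carcinoma (eHCC). Mef2d encodes a MADS-box transcription factor of the MEF2 family. The series title names tissue-resident macrophages and cancer precursors that express MEF2D, so the comparisons ask how macrophages, the other cells around them and cells of the hepatocyte lineage differed between the genotype labels at each stage, and between the stages within each label. The files hold 56458438 UMIs in 9672 barcodes for the KO premalignant library and 96593761 UMIs in 14167 barcodes for the WT premalignant library. They hold 93920711 UMIs in 10686 barcodes for the KO eHCC library and 118594527 UMIs in 11022 barcodes for the WT eHCC library. After filtering, 8819, 12868, 8368 and 9461 cells were kept in that order, with medians of 4311, 4774, 7266 and 8260 UMIs per cell. With 1 library per group there were no replicates, so no test between groups was run. Intervals are 95% intervals for counting error alone and do not cover differences between animals or preparations. Cell classes were named from marker genes and are called T-like, B-like and so on. The class of monocytes and macrophages other than Kupffer cells is called phagocyte-like.

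Over all kept cells, Mef2d RNA was higher, not lower, in the libraries labelled KO. It reached 101 CPM (UMI counts scaled to the total UMIs of the library; interval 98.2 to 104) in the KO premalignant library and 71.3 CPM (69.5 to 73.1) in the WT premalignant library, a log2 ratio of 0.50 (0.45 to 0.56; 1.42-fold). At eHCC the values were 96.3 CPM (94.1 to 98.5) in the library labelled KO and 61.2 CPM (59.7 to 62.7) in the library labelled WT, a log2 ratio of 0.65 (0.61 to 0.70; 1.57-fold), or 0.52 over all barcodes. Mef2d was also higher within large classes, so the mix of classes alone does not give the difference. In the premalignant KO and WT libraries it stood at 167.7 and 97.7 CPM in B-like, 107 and 71.3 in T-like and 90.8 and 71.0 in LSEC-like cells. At eHCC the values were 109.6 and 72.1 CPM in T-like and 105.9 and 59.35 in NK-like cells. In eHCC B-like cells they were 124.9 and 109.7 CPM, with intervals that overlapped. In eHCC phagocyte-like cells Mef2d differed by a log2 ratio of 0.77 (0.67 to 0.86), and in premalignant phagocyte-like cells by 0.17 (-0.18 to 0.51). Premalignant Kupffer-like cells had 6 UMIs in 31 KO cells (41.8 CPM) and 134 UMIs in 324 WT cells (39.9 CPM), a log2 ratio of 0.07 (-1.41 to 1.23). In the few premalignant hepatocyte-like cells Mef2d was lower in the library labelled KO: 15 UMIs in 15 cells (14.2 CPM, 7.95 to 23.4) against 29 UMIs in 43 cells (30.4 CPM, 20.3 to 43.6), a log2 ratio of -1.10 (-2.10 to -0.15). Both classes are under the 100 cells set for gene comparisons. The hepatocyte-like cells also came from different clusters: 14 of the 15 KO cells, but 21 of the 43 WT cells, were in a cluster with a median of 31624 UMIs per cell, and the others in one with a median of 2892. At eHCC this class held 0 Mef2d UMIs in 2 KO cells and 16 in 52 WT cells. In a cluster of low-UMI barcodes that carry hepatocyte RNA, Mef2d stood at 25.4 CPM in the KO and 20.7 CPM in the WT premalignant library, a log2 ratio of 0.30 (-0.36 to 0.95). The part of the gene that was deleted and the cell type in which it was deleted are not given in the sources used here. Tags that lie outside a deleted part would not show a deletion, so these values do not test the label. UMIs of variable segments of the T cell receptor came to 1.91% to 2.71% of those of its constant genes in the 4 libraries, few for tags at the 5' end, so where the tags lie in Mef2d is not settled here; the libraries are named below by their labels.

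In premalignant liver, Kupffer-like cells, the resident macrophages of the liver sinusoids, made up 0.352% of the cells of the library labelled KO and 2.52% of those of the library labelled WT. The log2 ratio was -2.84 (-3.42 to -2.31), from 31 and 324 cells. The RNA of Kupffer cell genes over all barcodes differed in the same direction. Clec4f, a lectin restricted to Kupffer cells, stood at 24.7 CPM against 292 CPM (log2 ratio -3.56, -3.64 to -3.48), and the efferocytosis receptor Timd4 at 2.73 against 28.2 CPM (-3.37). Vsig4, a complement receptor, had a log2 ratio of -3.69, the secreted scavenger protein Cd5l -3.97 and the scavenger receptor Marco -4.72; Cd5l and Marco were chosen after their values were seen. T-like cells had a higher share in the library labelled KO (23.9% against 14.8%; log2 ratio 0.69, 0.60 to 0.78), as did NK-like cells (4.54% against 1.87%; 1.28, 1.04 to 1.51). Cells like liver sinusoidal endothelium (LSEC-like) had a lower share (33.4% against 43.6%; -0.39, -0.45 to -0.32), and so did B-like cells (17.8% against 21.2%; -0.26, -0.35 to -0.17). Stellate or fibroblast-like cells were 54 against 25 (log2 ratio of shares 1.66, 0.95 to 2.40) and mast cell or basophil-like cells 45 against 21 (1.65, 0.87 to 2.47). Phagocyte-like cells made up 2.04% against 1.67%, with an interval that includes 0 (0.29, -0.01 to 0.58). Shares of 1 library sum to 1, so a class that is lower raises the others. The Kupffer-like ratio was -1.73 when each library was clustered on its own. Hepatocyte-like cells numbered 15 and 43 (log2 ratio of shares -0.97), and this ratio turned positive under 5 of the other settings.

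**Figure D1:**
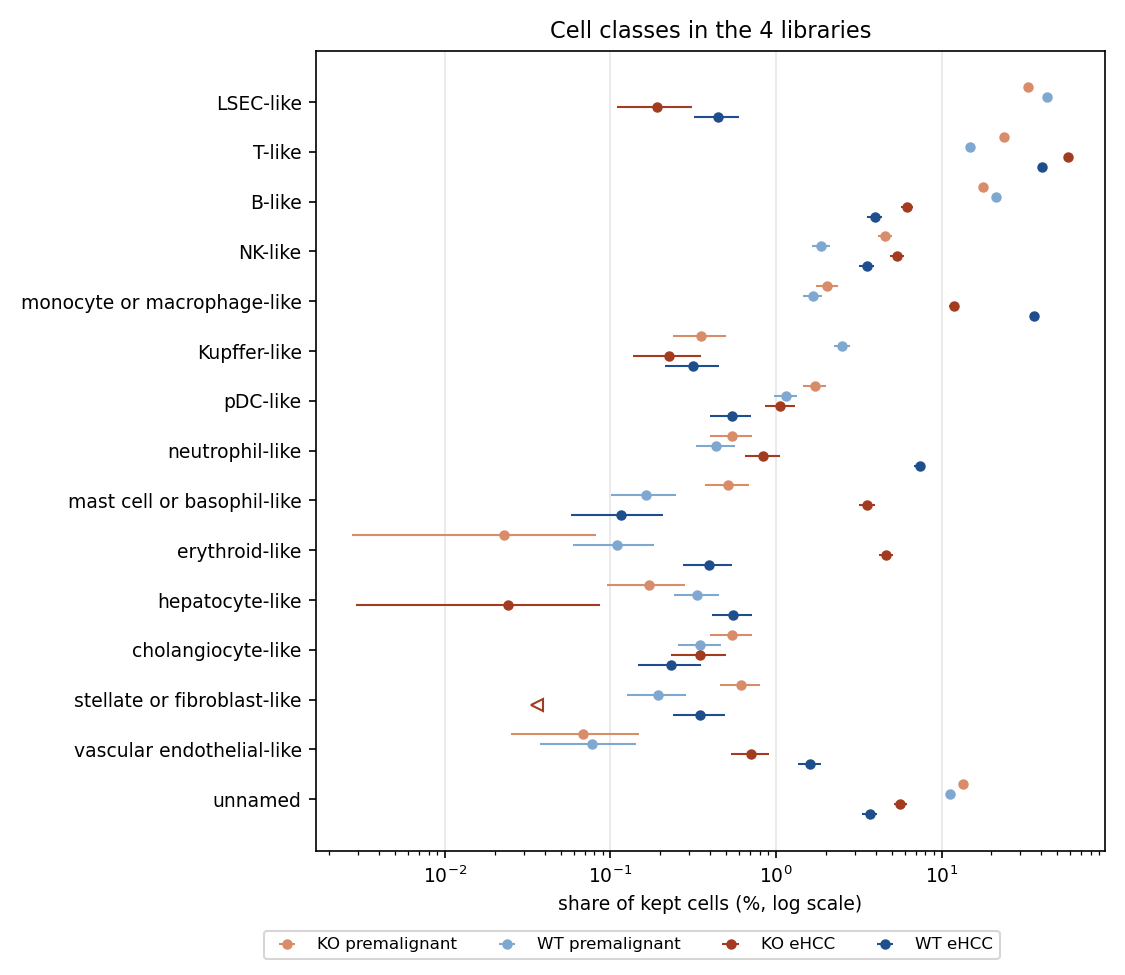
Share of kept cells (%, log axis) in each cell class for the 4 libraries; points are shares and bars their 95% Clopper-Pearson intervals, and the open triangle stands for 0 stellate or fibroblast-like cells in the KO eHCC library, drawn at a floor of 3 cells (0.0359%). Kupffer-like cells were lower in the KO than in the WT premalignant library (0.352% against 2.52%), and phagocyte-like cells, drawn as monocyte or macrophage-like, lower in the KO than in the WT eHCC library (11.8% against 36.1%).

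**Figure D2:**
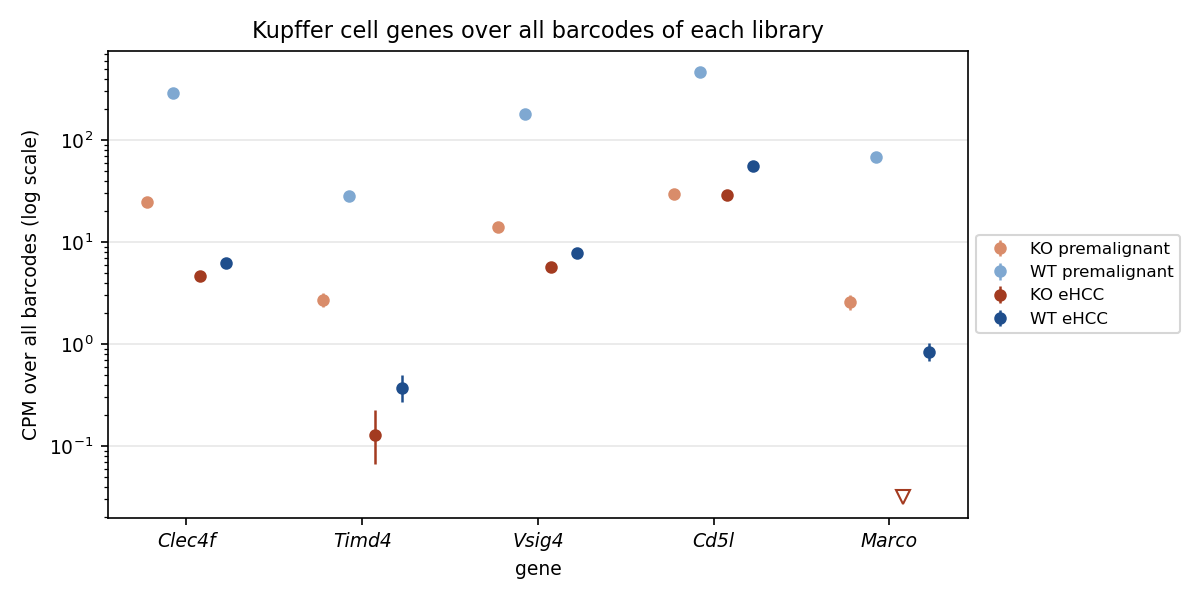
CPM over all barcodes (log axis) of 5 Kupffer cell genes in the 4 libraries; points are values of 1 library each, bars are exact Poisson 95% intervals, and the open triangle for Marco in the KO eHCC library, which had 0 UMIs, stands at a floor of 3 UMIs. Clec4f was at 292 CPM in the WT premalignant library and at 24.7 CPM or less in the other libraries.

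Premalignant lymphocytes of the library labelled KO had more RNA of immediate-early genes, which switch on within minutes of stimulation or tissue handling. The list's median log2 ratio was 0.41 in T-like cells, where 13 of 16 measured genes lay above 0. It was 0.39 in B-like cells (14 of 16) and 0.31 in NK-like cells (12 of 16; 0.16 with every cell thinned to 1000 UMIs). Fosb, a subunit of the AP-1 transcription factor, led with 1.61 (1.53 to 1.70; 3.06-fold) in T-like cells, 1.53 (1.45 to 1.61) in B-like cells and 1.45 (1.22 to 1.67) in NK-like cells. Heat shock genes were higher as well, with medians of 0.44 in B-like cells (12 of 12 genes), 0.27 in T-like cells (9 of 12) and 0.25 in NK-like cells (10 of 11). Hsph1, which encodes a chaperone, was 2.89-fold higher in B-like cells (1.53, 1.42 to 1.64) and 2.05-fold higher in T-like cells (1.04, 0.94 to 1.13). A list of MEF2 family members and known MEF2 targets had a median of 0.46 in T-like cells, with 15 of 17 genes above 0. It shares Jun, Egr1, Nr4a1 and Klf6 with the immediate-early list. Without these 4 genes, a setting added after the data were seen, its median was 0.50 (11 of 13). The shorter list still holds Mef2d itself (107 against 71.3 CPM in these cells) and Nr4a2 and Nr4a3, relatives of Nr4a1. Its median thus does not set MEF2 targets apart from the shift of immediate-early genes. Among its genes was Nr4a3, a nuclear receptor induced by antigen receptor signalling, at 1.15 (0.96 to 1.33; 2.21-fold). Type I interferon response genes, which limit virus replication, were lower: the median was -0.13 in T-like cells, -0.20 in NK-like cells, -0.23 in B-like cells and -0.66 in plasmacytoid dendritic-like cells. In the last class Isg15, a ubiquitin-like interferon-induced protein, was 3.62-fold lower (-1.86). After thinning, the interferon median was -0.03 in NK-like and -0.06 in B-like cells. Free RNA of hepatocytes moved with these groups: hepatocyte genes in the library labelled KO had a median of -0.64 in T-like cells, -0.72 in NK-like cells and -1.10 in B-like cells. Free RNA of erythroid cells was lower too, with a median of -2.79 in B-like cells (0 of 5 genes above 0) and the haemoglobin gene Hbb-bs at 22.1 against 231 CPM in T-like cells.

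Premalignant phagocyte-like cells of the library labelled KO had less RNA of phagocytosis genes (median -0.70; 14 of 18 below 0), of complement genes (-0.40) and of genes of lipid-associated macrophages (-0.65; 15 of 16 below 0). C1qb and C1qa, subunits of the first complement component, were 3.02-fold lower (-1.60, -1.75 to -1.45) and 2.58-fold lower (-1.37). Only 24 of 180 KO and 64 of 215 WT cells had a UMI of C1qb. A cluster led by F13a1 held 53.9% of the KO and 37.2% of the WT cells of this class. The values in this paragraph thus do not separate a different mix of cells from changes within cells. The lipid carrier Apoe was 2.14-fold lower (-1.10) and Trem2, a lipid-sensing receptor, 1.69-fold lower (-0.75, -1.08 to -0.44). The osteopontin gene Spp1 was 3.50-fold lower (-1.81), but 70.5% of its 247 WT UMIs and 61.0% of its 59 KO UMIs were in 1 cell each. Without the cell of each library with the most UMIs of the gene, a setting added after the data were seen, its ratio was -1.41 (-2.15 to -0.71). MHC class II genes, which present antigen to helper T cells, had a median of -0.42, with 7 of 10 below 0. H2-Eb1, one of them, was 1.46-fold lower (-0.55). Inflammatory genes were higher (median 0.34; 9 of 13 above 0): the neutrophil attractant Cxcl2 was 2.68-fold higher (1.42, 1.24 to 1.60), the inflammasome sensor Nlrp3 2.47-fold (1.31, 0.89 to 1.73) and the monocyte attractant Ccl2 1.75-fold (0.81, 0.57 to 1.05). Genes of monocyte-derived macrophages had a median of 0.26, with Fn1, which encodes fibronectin, at 2.18-fold (1.12, 1.01 to 1.24). Immediate-early genes (0.44; 14 of 16) and heat shock genes (0.28) were higher here too, type I interferon genes were lower (-0.33), and hepatocyte free RNA was at -0.45. Genes of Kupffer cell identity had a median of -1.25 in these cells, which came to 0.33 after thinning to 1000 UMIs. No phagocyte-like class was found in the KO library when each library was clustered on its own. The inflammatory median was 0.06 with genes of at least 5 counts included, and the monocyte-derived median 0.09 and the interferon median -0.15 after thinning. The complement median was farther from 0 under 6 settings, down to -1.47 with doublets kept.

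Premalignant LSEC-like cells of the library labelled KO had slightly more RNA of LSEC identity genes (median 0.16; 15 of 18 above 0) and less of endothelial adhesion genes (-0.27; 3 of 12 above 0) and type I interferon genes (-0.27; 6 of 23 above 0). Wnt9b, a Wnt ligand made by endothelium around the central vein, was 1.66-fold higher (0.73, 0.58 to 0.87) and the scavenger receptor Stab1 1.27-fold higher (0.35, 0.33 to 0.37). Cd34, a surface sialomucin of capillary endothelium, was 2.24-fold lower (-1.16, -1.35 to -0.98). The interferon-induced chemokine Cxcl10 was 1.54-fold lower (-0.62). Immediate-early genes had a median of -0.59 in these cells (2 of 16 above 0), with Egr1 at -0.94 and Fos at -0.89, while the MEF2 list had a median of 0.20 (13 of 17), and of 0.20 (11 of 13) without the 4 genes that both lists hold. Hepatocyte free RNA was at -0.75 and erythroid free RNA at -1.17 in LSEC-like cells. With each library clustered on its own, the immediate-early median was 0.15 and the adhesion median -0.01. The LSEC identity median was nearer 0 by more than 1.5 times under 5 settings. The libraries filled this class in different proportions. A cluster led by Wnt2 held 35.3% of the KO and 27.9% of the WT cells, and another, led by Clec4g and Dnase1l3, 14.2% and 29.7%. A cluster with a median of 1234 UMIs held 12.6% and 6.81%. These values thus do not separate a different mix of LSEC-like cells from changes within cells.

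No hepatocyte-like class reached the 100 cells set for gene comparisons, so hepatocyte genes were read in the low-UMI cluster, which held 930 KO and 887 WT premalignant barcodes and was chosen after the data were seen. There, RNA of oncofetal genes, which are active in fetal liver and liver tumours, was lower in the library labelled KO (median -0.85; 1 of 8 above 0). Afp, the fetal albumin-like plasma protein, was at 5 against 126 UMIs (-4.43, -6.08 to -3.17; 21.5-fold lower) and the mucosal peptide gene Tff3 at 24 against 545 UMIs (-4.28, -4.93 to -3.69). Plasma protein genes (-0.51; 4 of 22 above 0) and acute phase genes (-0.36; 5 of 14) were lower: the lipoprotein gene Apoa1 was 2.26-fold lower (-1.18) and the inflammation-induced apolipoprotein Saa1 2.94-fold lower (-1.55). Cytochrome P450 genes, which oxidise drugs and sterols, were higher (0.32; 15 of 17 above 0), and so were gluconeogenesis genes (0.35; 9 of 13) and urea cycle and amino acid genes (0.15; 16 of 20). Cyp2c50 was 2.23-fold higher (1.15, 0.76 to 1.56) and the tyrosine-degrading enzyme Tat 2.39-fold higher (1.26, 1.16 to 1.35). Alb, the albumin gene, was at 0.08 (0.03 to 0.13). Unfolded protein response genes (-0.44), cholesterol genes (-0.39) and ligands directed at macrophages (-0.63) were also below their random ranges. With each cell weighted equally, the oncofetal median was -0.31 (-3.30 with genes of at least 50 counts), the cholesterol median -0.13, the unfolded protein median -0.19 and the urea cycle median -0.01. The macrophage ligand median was -0.16 with genes of at least 50 counts.

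Of the 3 genes that the rule placed highest in premalignant phagocyte-like cells of the library labelled KO, Vegfa, the vascular growth factor, had 60 against 14 UMIs (log2 ratio 2.36; 5.12-fold). Single cells held most of the RNA of the other two. Prg4, which encodes lubricin, had 55 against 0 UMIs in 1 cell (at least 21.9-fold higher against a floor of 3 UMIs), and 89.8% of the 88 UMIs of the chemokine gene Ccl22 were in 1 cell (5.13, 3.54 to 7.44; 1.86 with at most 10% mitochondrial UMIs). Among the lowest, 67.7% of the WT UMIs of Jchain and 83.6% of those of Mzb1, both genes of antibody-secreting cells, were in 1 cell (-8.25 and -5.26; -0.17 and -0.76 after thinning), and 51.9% of those of Gpnmb (-3.29, -4.33 to -2.41; -1.72 with doublets kept). Without the highest cells Mzb1 was at -3.13 and Gpnmb at -5.71. In LSEC-like cells Mctp1 was 8.20-fold higher (3.04, 2.53 to 3.57), Tenm1 5.03-fold higher (2.33) and the semaphorin Sema3d 2.58-fold higher (1.37). The chemokine Ccl20 was lower with 2 against 74 UMIs, 41.9% of the latter in 1 cell (-3.83, -6.90 to -1.92; -2.34 with each library clustered on its own), Cdk5rap1 was 4.90-fold lower (-2.29), and the platelet chemokine Ppbp had a ratio of -2.43 that became 0.03 with each library clustered on its own. In T-like cells, beside Fosb, the mitochondrial tRNA synthetase gene Lars2 was 2.34-fold higher (1.23) and Atp8b2 2.51-fold higher (1.33), while Sostdc1 was 5.75-fold lower (-2.52; UMIs in only 9 KO and 12 WT cells, with 55.0% and 26.6% of them in 1 cell), Cdk5rap1 3.81-fold lower (-1.93) and Gipc1 2.05-fold lower (-1.04). Foxp3, the regulatory T cell factor, was at -1.09 (-1.66 to -0.53) in T-like cells, the inhibitory receptor gene Pdcd1 at -0.03 (-0.23 to 0.17), and Gzmb, a cytotoxic granule protease, at -0.22 (-0.30 to -0.15). For this comparison 63 medians were computed outside the free RNA lists and the low-UMI cluster. Of these, 14 lay above and 18 below the middle 95% of 10000 random lists matched on expression. Lists of independent genes would place 3.15 outside. Members of a list can move together and the classes share libraries, so an excess over this number is not evidence against chance. Scaling by median of ratios or TMM moved the median gene by -0.12 in B-like cells and by less than 0.1 in the other classes.

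At eHCC, phagocyte-like cells made up 11.8% (interval 11.2 to 12.5) of the library labelled KO and 36.1% (35.1 to 37.1) of the library labelled WT (log2 ratio -1.61; 991 and 3414 cells). Neutrophil-like cells made up 0.837% against 7.37% (-3.14, -3.52 to -2.78). T-like cells had a higher share in the library labelled KO (57.8% against 40.7%; 0.51, 0.44 to 0.57), as did B-like cells (6.23% against 3.94%; 0.66) and NK-like cells (5.39% against 3.54%; 0.61). Mast cell or basophil-like cells were 297 against 11 (log2 ratio of shares 4.93, 4.07 to 5.95), with 235 and 1 of them in a cluster led by Mcpt4 and Cma1, and erythroid-like cells 388 against 37 (3.57, 3.08 to 4.10). Hepatocyte-like cells were 2 against 52 (-4.52, -7.61 to -2.60), and stellate or fibroblast-like cells 0 against 33, where a floor of 3 of 8368 cells is a share of 0.0359% and the Clopper-Pearson upper limit of 0 cells is 0.0441%. Kupffer-like cells were few in both, 19 and 30 (-0.48, -1.39 to 0.39). The 2 libraries filled the T-like, B-like and phagocyte-like classes mostly from different clusters: the largest cluster held 56.5% of the T-like cells in the KO library and another held 37.6% in the WT library. NK-like cells were in the same cluster in both. With an earlier version of the naming rule, which left few KO phagocyte-like cells, their ratio was -6.97.

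Interferon response genes were higher in all 4 eHCC classes compared. Type I interferon genes had a median log2 ratio of 2.49 in phagocyte-like cells and 1.40 in T-like cells, with 23 of 23 genes above 0 in both, 1.76 in NK-like cells (23 of 23) and 0.80 in B-like cells (17 of 19). In phagocyte-like cells Isg15 was 13.8-fold higher (3.79, 3.72 to 3.85; 652 against 47.2 CPM) and Irf7, a transcription factor that amplifies interferon output, 10.4-fold higher (3.37, 3.30 to 3.44). Interferon-gamma response genes (1.87; 16 of 18) and MHC class I genes (1.17; 16 of 17) were higher in these cells, where Cxcl10 was 7.68-fold higher (2.94, 2.88 to 3.01) and the nonclassical class I gene H2-Q7 6.71-fold higher (2.75, 2.66 to 2.84). In T-like cells the antiviral enzyme gene Rsad2 was 5.19-fold higher (2.38, 2.23 to 2.52), and in NK-like cells Ifi27l2a was 17.2-fold higher (4.11, 3.71 to 4.53). In B-like cells Isg15 had 117 against 9 UMIs (3.13, 2.16 to 4.30). The B-like median was 0.14 and the NK-like median 1.06 after thinning to 1000 UMIs. Free RNA differed between the 2 libraries: hepatocyte genes had a median of -4.58 in T-like, -4.42 in NK-like, -4.32 in B-like and -1.49 in phagocyte-like cells, and erythroid genes 4.38, 6.01, 3.49 and 5.95 in that order.

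Phagocyte-like cells of the KO eHCC library had more RNA of genes of monocyte-derived macrophages and less of phagocytosis and lipid-associated genes. The 2 libraries filled this class mostly from different clusters. The largest in the KO library held 40.2% of its cells and only 32 WT cells. Another held 29.9% of the WT cells and only 5 KO cells. Genotype ratios of eHCC phagocyte-like cells thus do not separate a different mix of cells from changes within cells. Ly6c2, a surface protein of classical monocytes, was 9.37-fold higher (3.23, 3.18 to 3.27; 1031 against 110 CPM), in a list with a median of 0.85 and 9 of 14 genes above 0. Ccr2, a member of the same list, was lower (-0.36). The phagocytosis list had a median of -0.79 (3 of 19 above 0): Stab1 was 7.19-fold lower (-2.85, -3.03 to -2.67) and Mertk, a receptor for apoptotic cells, 4.20-fold lower (-2.07). Trem2 was 6.21-fold lower (-2.63, -2.71 to -2.56; 107 against 667 CPM) and Apoe 6.87-fold lower (-2.78, -2.79 to -2.77), in a lipid-associated list with a median of -0.53 and 7 of 16 genes above 0. Complement genes had a median of -0.45 (6 of 14 above 0) and MHC class II genes of -0.40 (0 of 11 above 0), with the invariant chain gene Cd74 1.45-fold lower (-0.54). Glycolysis and hypoxia genes were higher (0.89; 18 of 19 above 0), among them the lactate exporter Slc16a3 at 4.80-fold (2.26) and Vegfa at 3.51-fold (1.81, 1.73 to 1.90). Immune checkpoint ligands had a median of 0.58 (9 of 15 above 0), and Cd274, which encodes PD-L1, was 4.98-fold higher (2.32; 112 against 22.5 CPM). Immediate-early genes had a median of -0.98 (2 of 16 above 0). Kupffer identity genes had a median of 0.56 (14 of 17 above 0), led by Spic, a factor of iron-recycling macrophages, at 5.62-fold (2.49). Timd4 had 4 against 20 UMIs (-0.17, -2.18 to 1.40), Vsig4 was at 1.01 (0.80 to 1.22) and Clec4f at 0.56 (0.26 to 0.85), which came to 0.37 (0.11 to 0.63) and -0.27 (-0.74 to 0.18) without the highest cell of each library. The lipid-associated median was -0.29 with each library clustered on its own, where the Kupffer identity median was 3.38. The checkpoint ligand median was 0.26 with each cell weighted equally, and the mean of the complement list was -0.21.

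T-like cells of the KO eHCC library had more RNA of exhaustion genes, which mark chronically stimulated T cells (median 0.95; 13 of 15 above 0), of cytotoxic genes (0.28; 13 of 19), of glycolysis genes (0.55; 18 of 19) and of G2/M phase genes (0.52; 18 of 20), while S phase genes lay within their random range (0.05; 12 of 20). Gzmb was 5.53-fold higher (2.47, 2.41 to 2.52; 646 against 117 CPM) and its relative Gzma 3.41-fold higher (1.77, 1.72 to 1.82). The inhibitory receptor gene Lag3 was 3.42-fold higher (1.77, 1.65 to 1.90) and Tnfrsf9, a costimulatory receptor, 3.52-fold higher (1.82, 1.68 to 1.95). Pdcd1 was higher by a log2 ratio of 0.97 (0.90 to 1.04; 156 against 79.9 CPM). The regulatory T cell list had a median of 0.46 (7 of 12 above 0) and a mean of -0.01, with Foxp3 2.01-fold lower (-1.01, -1.28 to -0.74) and the interleukin receptor gene Il2ra 2.94-fold lower (-1.56, -1.73 to -1.38). In NK-like cells Gzmb was 6.11-fold higher (2.61, 2.47 to 2.76; 1187 against 194 CPM), G2/M genes had a median of 1.12 (8 of 9 above 0), and Ifng, which encodes interferon-gamma, was 1.69-fold lower (-0.76, -0.92 to -0.59). The cytotoxic list (0.06; 10 of 19 above 0) and the S phase list (0.03; 10 of 19) lay within their random ranges in NK-like cells. Immediate-early genes were lower in T-like (-0.51), NK-like (-0.90) and B-like cells (-0.58). Fos, an AP-1 subunit, was 4.65-fold lower in T-like cells (-2.22, -2.26 to -2.18) and 8.28-fold lower in NK-like cells (-3.05, -3.18 to -2.92). B cell activation genes had a median of -0.39 (5 of 14 above 0; mean -0.75), with the growth regulator Myc 2.38-fold lower (-1.25). The cytotoxic median in T-like cells was 0.18 and the G2/M median 0.98 after thinning to 1000 UMIs. A cluster led by Ccl5, Cd3d and Cd8a held 56.5% of the KO and 4.62% of the WT T-like cells. One led by Cd8b1 and Lef1 held 21.7% of the WT cells. Of the B-like cells, 1 cluster held 95.2% in the KO library and another 89.3% in the WT library. The T-like and B-like values of this paragraph thus do not separate a different mix of cells from changes within cells. An unnamed cluster led by proliferation genes and with T cell markers (239 KO and 142 WT cells) is not in the T-like class.

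**Figure D3:**
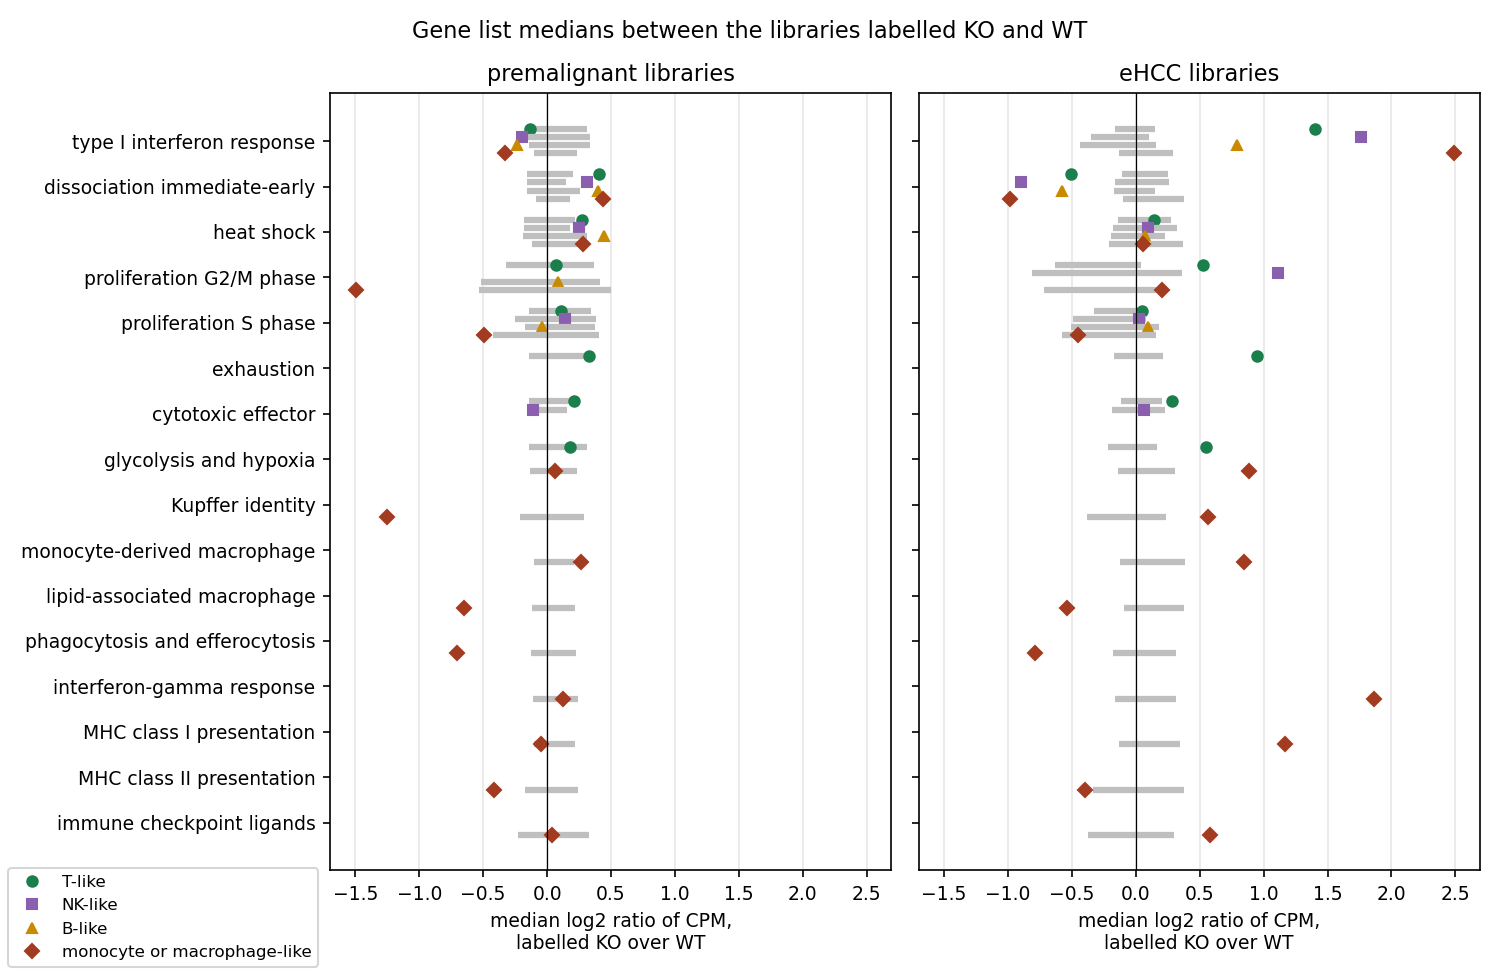
Median log2 ratio of CPM, KO over WT (horizontal axis), of 16 gene lists in 4 cell classes, premalignant libraries on the left and eHCC libraries on the right; points are list medians and grey bars the range of the middle 95% of random lists matched on expression. Type I interferon medians lay between -0.33 and -0.13 in the premalignant classes drawn and between 0.80 and 2.49 in the eHCC classes, where immediate-early medians lay between -0.98 and -0.51; monocyte or macrophage-like cells are the phagocyte-like cells of the text.

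By the naming rule, Wnt11 (109 against 4 UMIs; 6.92, 5.52 to 8.82; 2.79 after thinning), Mgarp (4.93) and the interferon-induced gene Ifi205 (3.99; 15.9-fold) were highest in eHCC phagocyte-like cells of the library labelled KO. Fcrls (80.1-fold lower, -6.32), Spp1 (37.1-fold lower, -5.21) and the signalling inhibitor Pmepa1 (38.1-fold lower, -5.25) were lowest there. Fcrls was also among the 10 leading genes of the largest phagocyte-like cluster, in which nearly all cells were from the WT library. In T-like cells Gcg, the glucagon gene, had 444 against 0 UMIs (at least 105-fold higher against a floor of 3 UMIs), with 70.1% of them in 1 of 20 cells. Foxq1 had 177 against 3 UMIs (5.39, 3.82 to 7.68; 2.76 after thinning) and Ppp1r3g 84 against 1 (5.90, 3.38 to 11.22). The collagen genes Col1a2 and Col1a1 were lowest, with 3 against 190 UMIs (-6.48, -8.77 to -4.91) and 9 against 226 UMIs (-5.14). Col1a1 stood at 8.43 CPM in T-like, 12.7 CPM in NK-like, 15.5 CPM in B-like and 6.01 CPM in phagocyte-like cells of the WT eHCC library. Its 226 UMIs in T-like cells were spread over 207 cells. Such a spread over cells and classes is what free RNA would give, so the collagen ratios are not read as changes in T-like cells. Stellate or fibroblast-like cells were 0 in the KO and 33 in the WT library. The limit on free RNA in the naming rule thus had no such class to compare with in the KO library. Ffar2, a receptor for short-chain fatty acids, had 3 against 121 UMIs (-5.83). In B-like cells Vps37b was 5.96-fold higher (2.58, 2.37 to 2.79), Rnf125 had 48 against 2 UMIs (4.02, 2.09 to 7.10) and the transcription factor gene Crem was 5.11-fold higher (2.35). Tbc1d9 was 20.4-fold lower (-4.35), the glucocorticoid-induced gene Fkbp5 6.91-fold lower (-2.79) and the heat shock gene Hspa1b 5.13-fold lower (-2.36). Of 46 medians computed at eHCC, 17 lay above and 9 below their random ranges, where lists of independent genes would place 2.3 outside. Scaling by median of ratios or TMM moved the median gene by 0.11 to 0.15 in the lymphoid classes.

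In the libraries labelled WT, phagocyte-like cells made up 1.67% of premalignant and 36.1% of eHCC cells (log2 ratio of eHCC over premalignant 4.43, 4.23 to 4.64). Each stage of a label is 1 library. A difference between stages thus cannot be told apart from one of animal, tissue sampled or preparation, here and for the libraries labelled KO. Neutrophil-like cells were higher at eHCC (4.08, 3.69 to 4.50), and T-like cells (1.46) too. Among immune cells alone the phagocyte-like ratio was 3.35 and the T-like 0.38. LSEC-like cells (43.6% to 0.444%; -6.62), Kupffer-like cells (-2.99, -3.58 to -2.45) and B-like cells (-2.43) were lower. WT phagocyte-like cells had more RNA at eHCC of lipid-associated genes (median 1.18; 13 of 16 above 0), with Trem2 4.79-fold higher (2.26, 2.08 to 2.44) and Apoe 6.06-fold higher (2.60), and of phagocytosis genes (1.13; 14 of 20), with C1qa 5.32-fold higher (2.41). They had more of inflammatory genes (0.69; 12 of 16 above 0) and less of type I interferon genes (-1.60; 0 of 23 above 0), interferon-gamma genes (-1.20) and MHC class I genes (-1.03). In WT T-like cells genes of naive T cells had a median of -1.31 (1 of 14 above 0), with the stem-like factor Lef1 4.29-fold lower (-2.10) and the lymph node homing receptor Ccr7 at -2.37, while T cell activation genes had a median of 0.41 (10 of 14). A cluster led by Lef1, Dapl1 and Tcf7 held 26.1% of the WT T-like cells at the premalignant stage but only 46 of 3853 at eHCC, where another cluster held 37.6%. Pdcd1 was 1.83-fold higher (0.87, 0.72 to 1.02) and Gzmb 2.61-fold lower (-1.38). In WT NK-like cells cytotoxic genes had a median of -0.90 (2 of 18 above 0), with Gzmb 9.17-fold lower (-3.20, -3.35 to -3.04). By the naming rule, Fcrls (9.10), Pmepa1 (5.17) and Spp1 (4.38) were highest in phagocyte-like cells and Jchain (-10.03), Mzb1 (-7.23) and S1pr5 (-5.86) lowest. At the premalignant stage Fcrls had 1 UMI, and 1 cell held 70.5% of the UMIs of Spp1, 67.7% of those of Jchain and 83.6% of those of Mzb1; without the highest cells these 3 ratios were 6.09, -8.52 and -4.81. Hepatocyte free RNA had a median of -1.80 in phagocyte-like, -1.19 in T-like and -2.16 in NK-like cells between these stages. The Kupffer-like ratio was 0.26 at a clustering resolution of 0.5, the NK-like share, at 0.92, was -0.16 among immune cells alone, and the phagocytosis list had a mean of 0.25. The 2 stages filled the phagocyte-like class mostly from different clusters, the largest of which held 37.2% of its cells at the premalignant stage and another 29.9% at eHCC. The inflammatory list had a mean of 0.44 and the T cell activation list of 0.25, and Jchain and Mzb1 were at -1.74 and -4.08 with each library clustered on its own. Of 46 medians, 14 lay above and 9 below their random ranges (2.3 for lists of independent genes).

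In the libraries labelled KO, phagocyte-like cells made up 2.04% of premalignant and 11.8% of eHCC cells (2.54, 2.31 to 2.77). At eHCC T-like cells were higher (1.28), and LSEC-like (-7.45) and B-like cells (-1.51) lower. Among immune cells alone the phagocyte-like ratio was 1.78, the T-like 0.52 and the B-like -2.27. Erythroid-like cells (7.68, from 2 and 388 cells) and mast cell or basophil-like cells (2.80) were higher. The latter class came from different clusters: 44 of its 45 premalignant cells were in a cluster led by Prss34 and Mcpt8, and 235 of its 297 eHCC cells in one led by Mcpt4 and Cma1. The Kupffer-like ratio, from 19 and 31 cells, depended on the setting: its interval included 0 over all cells (-0.63, -1.54 to 0.24) but not among immune cells alone (-1.39, -2.30 to -0.52), and it was 2.52 at a clustering resolution of 0.5. KO phagocyte-like cells had more RNA at eHCC of complement genes (median 1.30; 9 of 12 above 0; 0.83 with each cell weighted equally), type I interferon genes (1.23; 22 of 23), lipid-associated genes (1.04; 16 of 16) and glycolysis genes (0.85; 18 of 19). C1qa was 4.61-fold higher (2.21, 2.07 to 2.35), Isg15 4.50-fold higher (2.17), Cd274 2.42-fold higher (1.28, 0.93 to 1.64) and Trem2 at 0.38 (0.11 to 0.66). Immediate-early genes had a median of -1.20 (1 of 16 above 0), with Fos 3.30-fold lower (-1.72). In KO T-like cells type I interferon genes (1.37; 22 of 23 above 0), G2/M genes (0.98; 19 of 20) and exhaustion genes (0.80; 10 of 15) were higher and naive T cell genes lower (-1.01; 0 of 14). Pdcd1 was 3.65-fold higher (1.87, 1.73 to 2.01), Gzmb 2.47-fold higher (1.31) and Lef1 3.62-fold lower (-1.85). By the naming rule, the chemokine Ccl8 (2400 against 0 UMIs, at least 97.4-fold higher), the elastase Mmp12 (5.17) and Spon1 (458 against 0 UMIs, at least 18.6-fold higher) were highest in phagocyte-like cells, and Prg4 (-7.23), Ccl22 (-5.50) and the sterol synthesis enzyme Sqle (17.7-fold lower, -4.15) lowest. At the premalignant stage Mmp12 had 9 UMIs, and 1 cell held all 55 UMIs of Prg4 and 89.8% of those of Ccl22 (-3.43 without the highest cells). The 2 stages filled both classes mostly from different clusters: the largest held 53.9% of the phagocyte-like and 27.8% of the T-like cells at the premalignant stage, and others held 40.2% and 56.5% at eHCC. Hepatocyte free RNA had a median of -5.30 in KO T-like and -1.85 in KO phagocyte-like cells, and erythroid free RNA of 6.47 and 7.55. The NK-like share, at 0.25, was -0.51 among immune cells alone, and vascular endothelial-like cells, at 3.37, were -1.24 with each library clustered on its own. The naive T cell median was -0.58 and the exhaustion median 1.23 under TMM scaling, and Ccl22 was at -2.17 with at most 10% mitochondrial UMIs. Of 47 medians, 26 lay above and 9 below their random ranges (2.35 for lists of independent genes). Scaling moved the median gene by 0.43 to 0.48 in lymphoid classes and by 0.23 in phagocyte-like cells, against 0.17 to 0.26 over the lymphoid and phagocyte-like classes of the WT libraries.

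The naming rule also took the genes that differed most in the same direction between the genotype labels at both stages. In T-like cells these were Ell2, an elongation factor (log2 ratios of 1.47 at the premalignant stage and 1.49 at eHCC), and Nr4a3 (1.15 and 1.33), both higher in the libraries labelled KO, and Cdk5rap1 (-1.93 and -0.89) and the calcium-dependent kinase Camk2b (-1.10 and -0.96), both lower. In phagocyte-like cells Vegfa (2.36 and 1.81) and Il1rn, which encodes the interleukin-1 receptor antagonist (1.70 and 1.99), were higher, and C1qb (-1.60 and -1.45) and Ms4a7 (-1.94 and -1.45) lower. In the KO premalignant library 66.4% of the Il1rn UMIs were in 1 cell, and without the highest cells its premalignant ratio was 0.32 (-0.28 to 0.92). Across genes, the genotype ratios at the 2 stages had a Pearson correlation of 0.227 in T-like cells (9476 genes), 0.216 in B-like cells, 0.075 in NK-like cells and 0.092 in phagocyte-like cells; genes are not independent replicates. The share of genes with the same sign was 52.9% in T-like, 53.2% in B-like, 49.3% in NK-like and 54.1% in phagocyte-like cells. After thinning, the T-like correlation was 0.13.

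Cells with at least 3 UMIs of proliferation genes, counted after thinning each cell to 1000 UMIs, made up 3.65% of the KO and 2.93% of the WT premalignant library, and 9.08% of the KO and 4.06% of the WT eHCC library. The log2 ratio of KO over WT was 0.32 (0.09 to 0.54) at the premalignant stage and 1.16 (0.98 to 1.34) at eHCC. Without thinning it was -0.07 and 0.30. The premalignant ratio was 0.01 (-0.34 to 0.37) with at least 5 UMIs and 0.14 (-0.08 to 0.37) with doublets kept. At eHCC these settings gave 1.29 and 1.12. By class, the eHCC shares were 6.24% (5.58 to 6.96) of KO and 3.45% (2.89 to 4.07) of WT T-like cells, and 0.812% and 0.627% with at least 5 UMIs, where the intervals overlapped. With at least 3 UMIs the intervals overlapped in NK-like (5.10% and 1.80%), B-like (1.35% and 0.809%) and phagocyte-like cells (1.15% and 0.916%). With at least 2 UMIs they were apart in T-like cells (19.2% to 21.5% and 11.3% to 13.4%). They were also apart in NK-like (12.3% to 19.2% and 5.41% to 11.6%) and phagocyte-like cells (4.56% to 7.67% and 3.11% to 4.42%), but not in B-like cells. Overlap of intervals does not show that shares are equal. With at least 3 UMIs the T-like, NK-like, B-like and phagocyte-like classes held 300, 23, 7 and 11 of the 746 KO cells counted. Most of those cells thus lay in other clusters, and the ratio over all cells does not describe 1 cell type. An unnamed cluster led by proliferation genes and with T cell markers held 239 KO and 142 WT eHCC cells. It is not in the T-like class, so T-like shares and T-like medians of phase genes leave these cells out. Free RNA also gives such UMIs, so these shares do not count cycling cells.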

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

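Of the tests in this part, those on free RNA, on subsets of cells and on the 10 highest cells were written before their results were seen, and the 2 Kupffer tests, the handling stress test and the cytochrome P450 test after. Differences between the stages in the genotype ratios were not tested, since each group is 1 library. They are listed because the ratio lay on opposite sides of 0 at the 2 stages.

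Kupffer-like cells were fewer in the KO than in the WT premalignant library. Removal by the cell filters is argued against by Clec4f over all barcodes, with a log2 ratio of -3.562 (-3.64 to -3.48). The naming of clusters as the whole cause is argued against by the share of cells with at least 5 Clec4f UMIs. It was 34 of 8819 against 494 of 12868, a log2 ratio of -3.316 (-3.86 to -2.81). Clec4f was itself required for the Kupffer name, so this count cannot tell absent cells from cells without Clec4f RNA. Vsig4, which the name did not require, gave -3.449 (-4.03 to -2.92) for the same count. With each library clustered on its own the ratio of Kupffer-like shares was -1.73, so clustering and naming affect its size. Loss of these cells in dissociation, the piece of tissue sampled, a difference of 1 animal and a wrong label stay open, since none was tested. A genotype effect may also give fewer such cells and is equally untested, and Mef2d RNA over all cells was not lower in this library.

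Type I interferon genes were higher in the KO eHCC library, with medians that were below 0 at the premalignant stage and above 0 at eHCC. The eHCC minus premalignant difference of medians was 2.824 in phagocyte-like, 1.534 in T-like, 1.964 in NK-like and 1.03 in B-like cells. Free RNA from 1 responding class was predicted to add a like amount everywhere. The KO minus WT difference in summed CPM was 15.02 times larger in phagocyte-like than in B-like cells. A responding class also holds its own RNA, so this ratio cannot argue against free RNA in the others. Among the others the difference was 2777 in T-like, 1351 in NK-like and 378 in B-like cells. Haemoglobin RNA (Hbb-bs at 15682 CPM in B-like and 4036 CPM in phagocyte-like KO cells) shows that free RNA itself differs by class. The test thus leaves free RNA open. More handling stress in the KO library is argued against by the immediate-early median of -0.5059 in T-like cells. The medians were also below 0 in NK-like (-0.90), B-like (-0.58) and phagocyte-like cells (-0.98). The test looks only for more stress in the KO library. Other differences in handling between the 2 libraries stay open. Different subsets of cells could account for part of it: within 1 T-like cluster the median was 0.182 (497 KO and 128 WT cells), but interferon genes lead that cluster, so it was split on the outcome, and other clusters gave 1.2, 0.75 and 0.74 in T-like and 1.76 in NK-like cells. An infection, 1 animal, the tissue sampled and genotype stay open and untested.

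Oncofetal genes were lower in hepatocyte RNA of the KO premalignant library (median -0.85). Less hepatocyte RNA of every kind in the low-UMI cluster is argued against as the whole cause by the cytochrome P450 median of 0.3183 in the same cluster, although plasma protein genes (-0.51; 18 of 22 below 0) and acute phase genes (-0.36) were lower there. A few cells may hold the difference: the 10 highest cells had 59.8% of the 1097 oncofetal UMIs of the WT library, against 31.7% of 205 in the KO library. Cells with such a UMI were 14.1% in the KO and 19.2% in the WT library at medians of 1212 and 1245 UMIs. A genotype effect and a patch of altered tissue in 1 library stay open.

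Immediate-early genes were above 0 at the premalignant stage and below 0 at eHCC: the difference of medians was -0.9139 in T-like, -1.207 in NK-like, -0.9724 in B-like and -1.42 in phagocyte-like cells. In phagocyte-like cells the difference was 1.812 for Kupffer identity genes and 1.702 for G2/M genes, both below 0 at the premalignant stage and above 0 at eHCC. Neither turn of sign held under every setting. The premalignant Kupffer identity median was 0.33 after thinning, and the eHCC G2/M median -0.079 with each library clustered on its own. The genotype ratio of shares differed between the stages by 0.9157 for B-like cells, by 5.83 for erythroid-like cells and, as a bound from 0 cells, by -4.938 for stellate or fibroblast-like cells. Gzmb was lower in the library labelled KO at the premalignant stage and higher at eHCC, by a difference of 2.688 in T-like and 3.307 in NK-like cells. Mef2a went the other way, by -0.7043 in T-like and -1.17 in NK-like cells, and so did Ifng in NK-like cells (-1.142), Cd274 in B-like cells (-1.09), and Ccr2 (-0.617) and Ccl2 (-1.131) in phagocyte-like cells. Barcodes left out for few genes enter only the values over all barcodes: in the KO eHCC library haemoglobin genes made up 92.58% of the UMIs of 1591 such barcodes, against 65.4% of 434 barcodes in the WT eHCC library, 42.6% of 52 in the KO premalignant and 57.4% of 239 in the WT premalignant library.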

How the results depend on the processing

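The naming versions, the Kupffer clusters with mixed markers, the Clec4f count, the single clusters, the low-UMI cluster, the removal of the highest cell of each library and the MEF2 list without immediate-early genes were chosen after seeing the data; the other settings were planned. Over all results and settings 3009 values stayed within the tolerance set for them, such as their interval, 362 moved beyond it and 45 more turned direction. Apart from the values given below, the moved ones included 86 of genes (65 nearer 0), 189 of list medians (73 nearer 0) and 49 of shares (16 nearer 0), among which 38 medians within their random range and 4 shares with an interval that included 0 also changed sign. No paired analysis was possible because each group is 1 library, so that no group has a second replicate number to pair; a fit with stage as a term was left out, not impossible. Cell number limits hepatocyte-like cells (15, 43, 2 and 52) and premalignant phagocyte-like cells (180 and 215). TMM scaling kept 32 of 32 called premalignant lists and 26 of 26 at eHCC; thinning kept 19 of 30 and 21 of 25, and clustering per library 13 of 19 and 25 of 26. Clustering per library found no phagocyte-like cells in the KO premalignant library, so it gives no value there. Of 18 genes named at the premalignant stage, thinning named 5 again, and of 18 at eHCC 7. Except where a setting itself shows the cause, the cause was not tested.

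Under TMM and median-of-ratios scaling, which moved all KO stage ratios upward, heat shock became 0.042 and 0.055 in NK-like cells (from -0.43), 0.022 and 0.037 in T-like cells (from -0.40), and G2/M in B-like cells 0.37 and 0.38 (from -0.07). That G2/M value was 0.33 with at least 1000 UMIs, 0.34 with at most 10% mitochondrial UMIs, 0.336 with doublets kept, 0.44 with cells weighted equally, 0.47 with clustering per library and 0.25 as a mean. Over all barcodes Mef2d at eHCC was 0.52 (from 0.65). The hepatocyte-like share between WT stages (0.72) was -0.71 with another seed and -0.71 at resolution 0.5, -2.82 with at least 1000 UMIs, -2.57 with at most 10% mitochondrial UMIs, -2.96 with doublets kept, -3.07 with clustering per library and -2.84 with thinning. Between premalignant libraries (-0.97) it was 0.59, 0.26, 0.62, 0.17 and 0.60 under the last 5 of these. With at least 1000 UMIs the stellate share between WT stages was -0.078 (from 0.84), and with at least 5 counts G2/M in phagocyte-like cells between KO stages was -0.13 (from 0.72). Premalignant Kupffer identity in phagocyte-like cells (-1.25) was -0.59 with at most 10% mitochondrial UMIs, -0.55 with doublets kept, -0.28 with cells weighted equally and 0.33 with thinning. The premalignant LSEC-like share (-0.39) was -0.57 with doublets kept and -0.31 with clustering per library. With cells weighted equally Kupffer identity between KO stages was -0.31 (from 0.58), glycolysis in T-like cells between WT stages -0.059 (from 0.061) and the urea cycle list -0.013 (from 0.15). As a mean, the eHCC regulatory T list was -0.0083 (from 0.46). With clustering per library Ppbp in LSEC-like cells was 0.033 (from -2.43), LSEC immediate-early 0.15 (from -0.59), complement between WT stages -0.11 (from 0.38), eHCC phagocyte G2/M -0.079 (from 0.20), S phase in NK-like cells between KO stages -0.11 (from 0.17), the vascular endothelial share between KO stages -1.24 (from 3.37), the premalignant Kupffer-like share -1.73 (from -2.84) and eHCC phagocyte interferon 1.72 (from 2.49; 2.23 with thinning). At resolution 0.5 the Kupffer-like share was 0.26 between WT stages (from -2.99) and -2.28 between premalignant libraries, and the eHCC phagocyte-like share -1.85 (from -1.61; -6.97 under naming version 1). Among immune cells the NK-like share was -0.51 between KO stages (from 0.25) and -0.16 between WT stages (from 0.92), the T-like share 0.60 at eHCC (from 0.51) and 0.46 at the premalignant stage (from 0.69), and the neutrophil-like share between KO stages -0.14 (from 0.62). Proliferation without thinning was 0.30 at eHCC (from 1.16) and -0.075 at the premalignant stage (from 0.32; -0.040 at 500 UMIs). With thinning, interferon in B-like cells between KO stages was -0.21 (from 0.31), the unfolded protein response in premalignant phagocyte-like cells 0.15 (from -0.20), and the T-like correlation between stages 0.13 (from 0.23).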

Other observations

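No hypothesis was tested in this part. Plasmacytoid dendritic-like cells had a higher share in the libraries labelled KO at both stages, with a log2 ratio of 0.59 (0.26 to 0.93; 152 and 147 cells) in premalignant liver and 0.98 at eHCC (89 and 51 cells). Immediate-early genes had a median of 0.30 in the premalignant cells of this class, with 14 of 16 genes above 0. Vascular endothelial-like cells were 59 in the KO and 151 in the WT eHCC library (-1.18), and cholangiocyte-like cells 48 and 45 in the premalignant libraries. In B-like cells, type I interferon genes were lower at eHCC than at the premalignant stage between the libraries labelled WT (median -0.77; 1 of 23 above 0; -0.21 after thinning).

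Mef2a, a relative of Mef2d, had log2 ratios of KO over WT of -0.93 in eHCC phagocyte-like cells, -0.24 (-0.33 to -0.16) in eHCC T-like cells and 0.46 (0.32 to 0.60) in premalignant T-like cells. Mef2c, the family member of B and myeloid cells, was at -1.37 in eHCC phagocyte-like cells and at 0.18 in premalignant LSEC-like cells. Csf1, a growth factor of macrophages, was at 0.16 in premalignant LSEC-like cells.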
